A study of Drosophila melanogaster with 3 samples.

How the data were processed

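Chromatin immunoprecipitation sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of mixed sex, aged 0 to 24 h, from a transgenic line that carries the protein CG10543 fused to enhanced green fluorescent protein (eGFP). Chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. There were 3 biological replicates, all of 1 group, so no comparison between groups was possible. The replicate numbers are those of the labels.

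For each replicate, for the pool of the 3 replicates and for an optimal set from the irreproducible discovery rate (IDR, a method that keeps peaks whose ranks repeat between replicates), the authors deposited a list of regions with a summit position. Each list was given on the dm6 and on the dm3 assembly. Every region has a signal value, the deposited measure of enrichment from the peak caller, and a −log10 q-value, also deposited by the authors. The replicates and the pool were called against the same single control alignment of each assembly, per the file headers. The aligner, the peak caller and their settings are not given in the sources used here. The replicate and pooled lists each hold 30000 regions, a length that takes in weak regions by construction. The files hold no read counts, so the sequencing depth of each sample is unknown, and intervals given for shares cover the counting of peaks or genes only.

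Signal values were used only to rank regions within a list. Genes, transcripts and coding sequence came from Ensembl release 115 for the BDGP6 assembly and sequence from the RefSeq copy of Release 6, which both use dm6 coordinates. All dm6 summits lay within the lengths of the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. No dm3 annotation was used, and dm3 lists entered only counts and overlaps. Transposable elements were left out of the gene set, which held 18164 genes, 13945 of them protein-coding, with 23998 distinct transcription start sites (TSSs).

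A summit within 500 bp of any TSS was counted as a TSS peak, and other summits took the annotation of their base. Distal peaks lay over 1000 bp from every TSS. A gene was called bound when an IDR summit lay within 500 bp of any of its TSSs. The background for annotation shares was the 20036 pooled regions that overlap no IDR peak, called weaker regions. For replicates, the 7545 regions with the highest signal were taken from each list, as many as there are IDR peaks, and 2 regions were called shared when their summits lay within 200 bp. Chance overlap came from 100 seeded circular shifts of the regions along each arm.

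Shares were compared with two-sided Fisher's exact tests and given with exact Clopper-Pearson 95% intervals. The 30 gene lists and the 34 motif consensus sequences were fixed before the data were examined, as were the tests of the report and the rule for naming genes. The alternatives were fixed then too, apart from those said to be chosen after seeing the data: the nearest TSS only, the most 5' TSS only, peaks recovered in all 3 replicates, arms without X and 4, the other side of each summit and 1 summit per interval. Of the list symbols, 9 matched no protein-coding gene and were dropped. Transfer RNA and small nuclear RNA genes were compared with all other genes, and the other lists with all other protein-coding genes. Head-to-head genes were protein-coding genes whose nearest upstream neighbour starts on the other strand within 1000 bp. Motifs and 6-mers were sought in windows of 100 bp on each side of the summit and in a paired window centred 500 bp away on a seeded random side, with exact McNemar tests. The 6-mers were found on arms 2L, 2R and 3L and had to pass again on 3R and X. Ranks of TSS and distal peaks were compared by a permutation test of medians with 100000 resamples. Values from many tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 within each family. Values of single replicates were computed from the 7545 strongest regions of each and are given as mean ± SD. P-values compare peaks, genes or windows within these 3 samples and do not measure the spread between embryo collections.

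The genes named were CG10543 itself, the genes nearest the 20 IDR peaks with the best mean rank over the replicates among peaks matched in all 3, and up to 4 members of each list with the highest pooled signal at a TSS. The 5 motifs and the 5 6-mers with the largest odds were named by the same rule. Other names were chosen after their values were seen.

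The tests were run on simulated data first. Lists of 90 genes made with odds of 4 were called in 100% of 100 simulations, lists of 20 genes in 90%. With odds of 2 these shares were 91% and 37%, so differences of that size in short lists were often missed. Lists with no difference were called in 5% and 2%. Each simulated list was called on its own unadjusted p-value, a looser rule than the adjusted one used for the gene lists. Shares under the adjusted rule were not measured and may be lower. Simulated genes were also drawn at random and bound independently, whereas neighbouring genes of real lists can share a summit. The simulated shares may therefore not hold for the real lists. In a single simulation, a motif planted in 5% of 7500 random windows was recovered with its 6-mers, and no other 6-mer was called. Both windows of each pair were random there, so this does not measure calls that come from differences in composition. Planted in 2% of windows, the motif was recovered but only 33.3% of its 6-mers were. Alternatives changed the overlap distance (100 or 500 bp, or intervals sharing 1 bp), the TSS distance (200 or 1000 bp), the peak set (the 3772 strongest, or peaks recovered without each replicate), the background, the window size (50 bp on each side) and the assembly. Peak sets without a replicate were not called anew. They held the IDR peaks of all 3 replicates that both other replicates recovered among their strongest regions, 4748 to 5360 peaks. The replicate left out thus still shaped them. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.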

Results

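Binding of CG10543 was mapped in whole embryos that carry a CG10543-eGFP fusion, in 3 biological replicates collected at 0 to 24 h of development. CG10543 is a fly gene known by its annotation symbol. The data have no second condition, so the questions were where the tagged protein was found, at which genes and sequences, and how far the replicates shared the regions. No sample without the tagged protein was analysed, so signal that does not depend on CG10543 cannot be told from its binding. The IDR set held 7545 peaks on dm6. Regions with a q-value under 0.01 numbered 12593 in replicate 1, 7016 in replicate 2 and 7612 in replicate 3.

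The gene of the tagged protein was itself among the bound genes. CG10543 (FBgn0034570, dm6 chromosome 2R, 20996220 to 21007740) held 5 IDR summits, all at intronic bases. The strongest lay at 20998010, 1369 bp from the nearest of its 3 TSSs, with a pooled signal of 1458 and rank 148 of the 7545 peaks. Its ranks in the replicates were 36, 492 and 648, and it shared the interval 20997124 to 20998362 with weaker summits. The summit at 21000341 ranked 2045, 26588 and 10658. This summit and the one at 21000126 lay within 500 bp of a TSS and so counted as TSS peaks. The line is transgenic for CG10543, and the copy number of the gene was not examined. The strongest region within 500 bp of a CG10543 TSS had its pooled summit at 21000126, 349 bp from the TSS at 21000475, and ranked 474 ± 158 (SD, n = 3) of the 30000 regions of a replicate. With the distance set to 200 bp this region was left out and the mean rank was 10749.

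**Figure D1:**
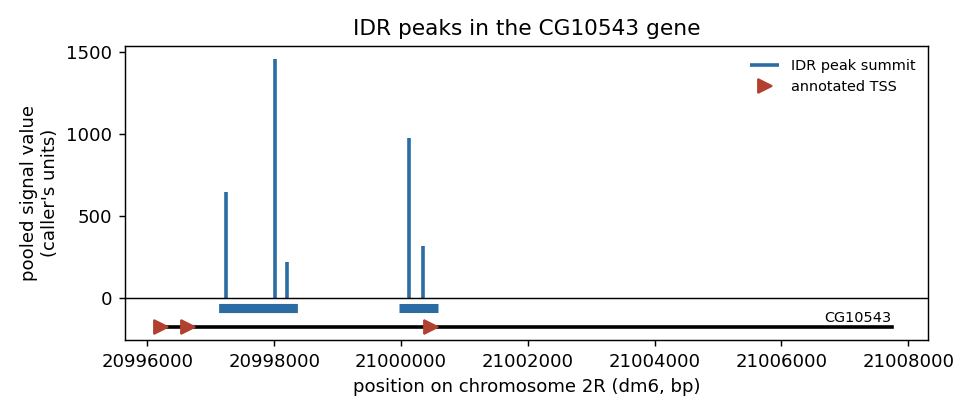
Pooled signal value of each IDR summit (vertical lines, in the units of the peak caller) along the CG10543 gene on chromosome 2R of dm6, with peak intervals as blue bars under the axis, the gene as a black line and its 3 TSSs as arrowheads. The 5 summits fall in 2 groups, and the highest, at 20998010, has a value of 1458.

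The strongest peaks lay at genes of varied function and often at intronic bases, some of them within 500 bp of a TSS. The best mean rank over the replicates, 4.67 ± 4.62 (SD, n = 3), belonged to a peak in an intron of CG11050 (2L, 6612376 to 6612955), 1028 bp from a TSS. The peak at the TSS of the noncoding RNA gene lncRNA:CR31840 (2L, 14023835 to 14024752) had a mean rank of 6.0 ± 2.65. An intronic peak of Trl, which encodes GAGA factor (3L, 14759185 to 14759906), had a mean rank of 7.0 ± 3.61, and an intronic peak of the kinase gene Tlk (X, 3741931 to 3743468) had 8.33 ± 0.577. The peak 97 bp from the TSS of CG14100 (3L, 19590407 to 19590836) had the highest pooled signal of all, 5430, and ranked 20 in replicate 1 and 1 in replicates 2 and 3. HmgZ, which encodes a high mobility group protein, was nearest to 3 of the 20 strongest peaks. The glycolytic genes Gapdh2 (X, 15867738 to 15868249) and Eno (2L, 1727656 to 1728182) had peaks 161 and 225 bp from a TSS. The other genes nearest these 20 peaks were cbt, CG9663, mRpL41, Pdrg1, Sox14, Lk6, Rh5, lncRNA:CR44761, lncRNA:CR44339 and lncRNA:CR44619. Of the 20 peaks, 10 lay within 500 bp of a TSS and 6 over 1000 bp away, and none ranked below 64 in any replicate.

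Regions within 500 bp of a TSS held most peaks. TSS peaks were 54.7% of the 7545 IDR peaks (4129; 95% interval 53.6 to 55.9%) and 24.1% of the 20036 weaker regions, an odds ratio of 3.80. The same class took 54.1% ± 2.32 (SD, n = 3) of the strongest regions of single replicates. With a TSS distance of 200 bp it held 41.3% of peaks and 15.3% of weaker regions. Introns held 33.2% of peaks and 50.2% of weaker regions (Fisher's exact test, adjusted p = 7.71e-144). Intergenic sequence held 8.85% of peaks and 18.1% of weaker regions (Fisher's exact test, adjusted p = 2.12e-87). Coding sequence was the rarest class among peaks, 0.517% against 3.10% of weaker regions (Fisher's exact test, adjusted p = 5.52e-46). Shares in 5' UTRs did not differ past the threshold (0.822% and 1.03%, Fisher's exact test, adjusted p = 0.133). The median distance from a summit to a TSS was 340 bp for peaks and 1957 bp for weaker regions.

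**Figure D2:**
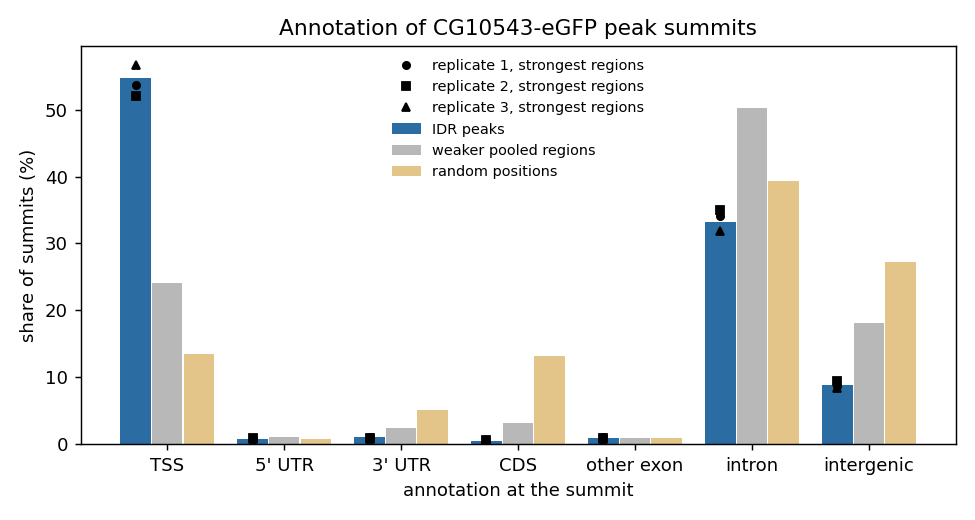
Share of summits in percent (vertical axis) by annotation (horizontal axis) for IDR peaks, weaker pooled regions and random positions, with the strongest regions of each replicate as black symbols. TSS peaks are 54.7% of IDR peaks against 24.1% of weaker regions and 13.5% of random positions.

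TSS peaks also ranked higher within the IDR set than distal peaks. The median percentile of pooled signal was 55.0 for 4129 TSS peaks and 43.1 for 2656 distal peaks, a difference of 11.9 percentile points (two-sided permutation test, p = 1e-05, the smallest that the resamples can give). The difference was 10.8 ± 4.63 (SD, n = 3) in single replicates, and TSS peaks were higher in 3 of 3. Without replicate 3 it was 7.19.

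Of the 13945 protein-coding genes, 3895 (27.9%; 95% interval 27.2 to 28.7%) were bound, and 18.2% counting only peaks recovered without replicate 3. Head-to-head genes, which share a promoter region with a neighbour on the other strand, were bound more often than other genes: 42.2% of 4480 against 21.2% of 9465, an odds ratio of 2.72 (95% interval 2.52 to 2.94; Fisher's exact test, p = 2.28e-142). The same summit can count for both genes of such a pair, so these genes are not independent. The interval and the p-value take no account of this and overstate the precision. The share of head-to-head genes was 33.4% in replicate 1, 44.2% in replicate 2 and 48.2% in replicate 3. Each was above the share of other genes. With each peak counted only for its nearest TSS, an alternative chosen after seeing the data, the shares were 26.8% and 19.1%, and without replicate 2 or replicate 3 the difference of 21.0 percentage points fell to 11.8 and 11.7. X-linked genes and autosomal genes, the latter on 2L, 2R, 3L and 3R without chromosome 4, were bound at shares of 28.1% (618 of 2196) and 28.0% (3267 of 11669). The odds ratio was 1.01 (95% interval 0.910 to 1.11; Fisher's exact test, p = 0.897). Among the 3772 strongest peaks, however, X-linked genes had the lower share, 15.8% against 18.05% (Fisher's exact test, p = 0.0114). That p-value is unadjusted, and the difference passed in no other setting run. In embryos of mixed sex X is present at a lower dose than autosomes, and the effect of this was not examined.

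Among the 30 gene lists, 7 were bound more often than other genes and 6 less often. Genes of cytoplasmic ribosomal proteins stood highest: 70 of 91 were bound (76.9%; 95% interval 66.9 to 85.1%) against 27.6% of other protein-coding genes (Fisher's exact test, adjusted p = 9.11e-21), and 78.4% ± 5.64 (SD, n = 3) in single replicates. RpS27, RpL7, RpL34b and RpL13A had the strongest TSS peaks of the list, at ranks 42, 78, 79 and 145 of the IDR set. Whether the signal at these genes depends on the tagged protein was not tested. Nuclear receptor genes followed with 13 of 21 (61.9%; 95% interval 38.4 to 81.9%; Fisher's exact test, adjusted p = 0.00503), led by the ecdysone-induced Eip75B at rank 292, Hnf4 at 466, Hr96 at 511 and ERR at 615. Genes of signalling pathways were bound in 26 of 44 cases (59.1%; 95% interval 43.2 to 73.7%; Fisher's exact test, adjusted p = 0.000121), with sgg, the fly GSK3 kinase, at rank 176, shn at 262, the EGF receptor ligand spi at 501 and its inhibitor aos at 687. Muscle genes reached 13 of 22 (59.1%; 95% interval 36.4 to 79.3%; Fisher's exact test, adjusted p = 0.00958), with TpnC73F at rank 419, the titin-like sls at 746, the transcription factor gene Mef2 at 1302 and Mlc2 at 1418.

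Polycomb and Trithorax group genes, which maintain silent and active chromatin states, were bound in 15 of 29 cases (51.7%; 95% interval 32.5 to 70.6%; Fisher's exact test, adjusted p = 0.0165). Their strongest peaks were at ph-p (rank 40), brm (67), E(z) (207) and Su(z)2 (417). Genes of mitochondrial ribosomal proteins had 32 of 73 bound (43.8%; 95% interval 32.2 to 55.9%; Fisher's exact test, adjusted p = 0.0111), with mRpL41 at rank 4 and mRpS10 at 25, ahead of mRpS23 at 88 and mRpL23 at 264. Translation factor genes had 23 of 53 bound (43.4%; 95% interval 29.8 to 57.7%; Fisher's exact test, adjusted p = 0.0465), with eIF6 at rank 26, eIF4EHP at 28, eEF1gamma at 158 and eIF1 at 307.

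The lower lists were mostly genes of differentiated tissues. Odorant and gustatory receptor genes had 0 of 119 bound (95% interval 0 to 3.05%; Fisher's exact test, adjusted p = 3.22e-16), and cuticle protein genes had 1 of 96, Cpr73D (Fisher's exact test, adjusted p = 8.13e-12). Testis genes had 0 of 20 bound (95% interval 0 to 16.8%; Fisher's exact test, adjusted p = 0.00758) and eggshell genes 0 of 18 (95% interval 0 to 18.5%; Fisher's exact test, adjusted p = 0.0164). Transfer RNA genes had 29 of 290 bound (10%; 95% interval 6.80 to 14.0%) against 24.1% of all other genes (Fisher's exact test, adjusted p = 9.01e-09). The strongest of these, tRNA:Ala-TGC-2-1, tRNA:Tyr-GTA-1-8, tRNA:Trp-CCA-2-2 and tRNA:Thr-AGT-1-2, ranked 100, 134, 624 and 846. These genes also occur in similar copies in which reads may not be placed, so their share is uncertain. The genes they were compared with were mostly protein-coding. Shares were also low for noncoding RNA genes (11.5%), small nuclear RNA genes (12.5%) and small nucleolar RNA genes (8.55%). The call against all other genes thus does not set transfer RNA genes apart from these classes. Replication-dependent histone genes had 0 of 111 bound (Fisher's exact test, adjusted p = 2.36e-15), but they are near-identical copies in which reads may not be placed, and 0 of the 111 had any pooled region at a TSS, so their value is uncertain.

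The 17 remaining lists did not pass the threshold. Aminoacyl-tRNA synthetase genes (50% bound) and genes of architectural and insulator proteins (48.0%, with Cp190 at rank 63, Chro at 80, Dref at 178 and M1BP at 321) had the highest shares among them, with adjusted p of 0.121 and 0.0884 in Fisher's exact tests. The architectural and insulator list was called higher with the 3772 strongest peaks, without replicate 1 and with a TSS distance of 200 bp, with adjusted p of 0.0304, 0.0467 and 0.037 in exact tests. In alternatives chosen after seeing the data, the synthetase list was called higher without X and 4 (60% against 28.0%, Fisher's exact test, adjusted p = 0.0384) and had 11.1% against 21.6% with each peak counted only for its nearest TSS. Heat shock genes had a share of 45.0%, led by Hsp83 at rank 41, dorsoventral patterning genes 41.7%, RNA splicing factors 41.4%, segmentation genes 40.7%, led by hry at rank 102, and neurogenesis regulators 40.0%. DNA replication and cell cycle genes had a share of 31.1%, terminal neuronal genes 30%, led by elav at rank 23, germ line genes 30%, Hox genes 25% and oxidative phosphorylation genes 23.3%. Gut genes had 21.1%, led by fkh at rank 71, proteasome genes 20.8%, blood and fat body genes 20%, led by ush at rank 208, small nuclear RNA genes 12.5%, led by snRNA:7SKa at rank 33, and dosage compensation genes 0 of 6.

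The calls depended on the background and on the peaks counted. Against genes with any pooled region at a TSS, cytoplasmic ribosomal protein genes were the only list still called higher (86.4% against 56.6%, Fisher's exact test, adjusted p = 1.69e-07), and cuticle protein and transfer RNA genes were called lower. Nuclear receptor genes had a share as high there (86.7% of 15 genes) and Polycomb and Trithorax group genes 78.9%, but these short lists did not pass (Fisher's exact tests, adjusted p = 0.132 and 0.244). Histone, testis and eggshell genes have no member in that background and could not be tested, and odorant and gustatory receptor genes have 4. With each peak counted only for its nearest TSS, again chosen after seeing the data, mitochondrial ribosomal protein genes had a share of 19.2% against 21.6% of other genes, and translation factor genes (32.1% against 21.5%, Fisher's exact test, adjusted p = 0.125) and eggshell genes (adjusted p = 0.0539) also lost their calls. The count of higher lists was 4 without replicate 3. Each replicate was left out in turn by keeping only IDR peaks that both other replicates recovered. The cytoplasmic ribosomal protein, signalling pathway and Polycomb and Trithorax group lists then stayed higher in each case. The receptor, cuticle, histone and transfer RNA lists stayed lower. The other called lists (mitochondrial ribosomal protein, translation factor, muscle, nuclear receptor, testis and eggshell genes) each lost the call without at least 1 replicate. These sets also hold fewer peaks, so a lost call cannot be laid to the replicate alone. Without replicate 3 the share of muscle genes was 27.3% and that of translation factor genes 28.3%, against 18.2% of other genes, and without replicate 2 that of mitochondrial ribosomal protein genes was 21.9% against 19.3%. Nuclear receptor genes had 42.9% against 22.5% without replicate 1. Testis and eggshell genes stayed at 0%, and only the share of other genes fell. With only the most 5' TSS of each gene, nuclear receptor and Polycomb and Trithorax group genes also lost it.

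**Figure D3:**
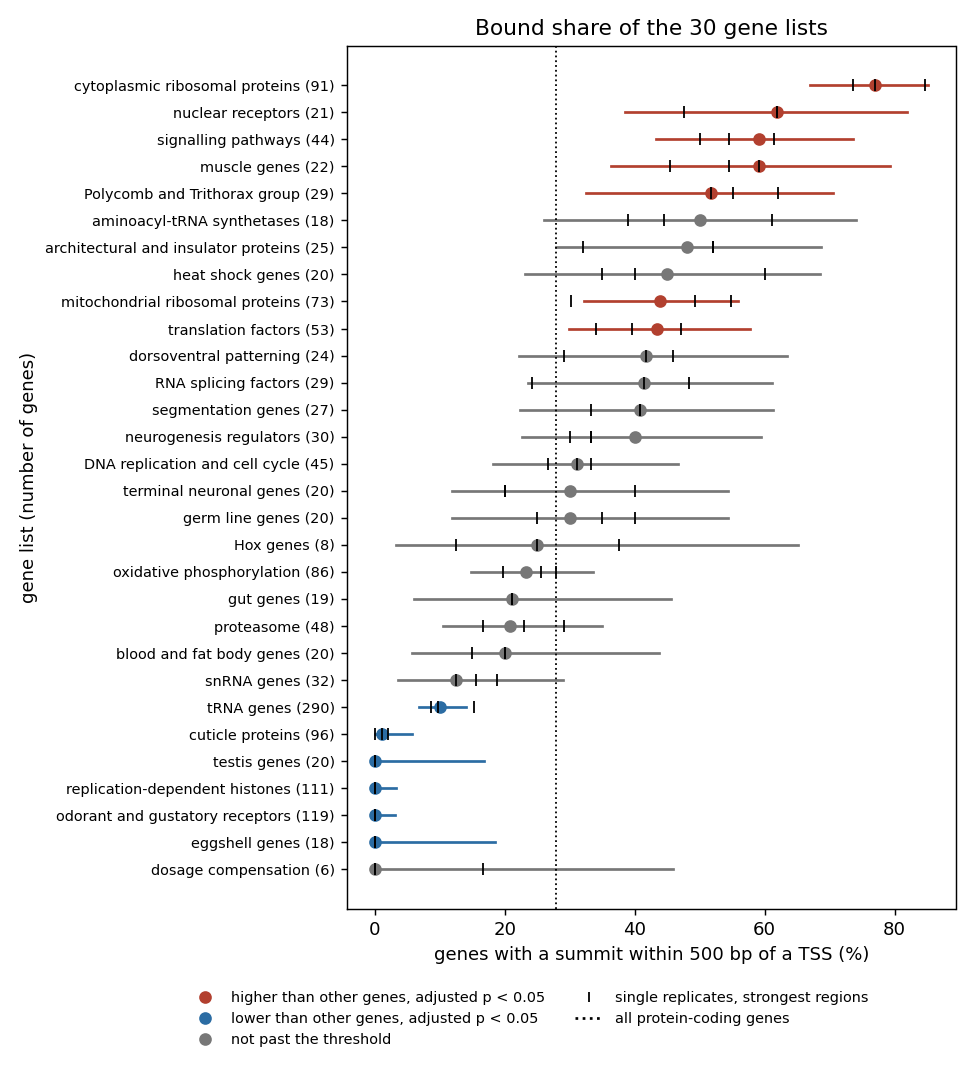
Percent of the genes of each list with an IDR summit within 500 bp of a TSS (points, horizontal axis) with exact 95% intervals (lines), the values of single replicates (ticks) and the share of all protein-coding genes (dotted line, 27.9%). Cytoplasmic ribosomal protein genes are highest at 76.9%, and 5 lists have 0% bound.

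Of 34 motifs, 15 were more frequent at summits than 500 bp away and 7 were less frequent. The 5 with the largest odds were the BEAF-32 site pair (CGATANNNNNNCGATA), Motif 1 (GGTCACACT, bound by M1BP), the DNA replication-related element DRE (TATCGATA), the cAMP response element CRE (TGACGTCA) and the CTCF core (AGRKGGCGC). DRE was found in 2.33% of 7545 summit windows and 0.702% of flank windows, odds of 3.37 (95% interval 2.47 to 4.59; exact McNemar test, adjusted p = 1.06e-15). Motif 1 was found in 1.46% and 0.345%, odds of 4.23 (95% interval 2.76 to 6.49; exact McNemar test, adjusted p = 9.66e-13). The BEAF-32 pair was found in 13 summit and 3 flank windows (exact McNemar test, adjusted p = 0.0329), CRE in 47 and 22 (exact McNemar test, adjusted p = 0.0067) and the CTCF core in 104 and 49 (exact McNemar test, adjusted p = 2.92e-05). The smallest p belonged to the Zeste site, in 35.2% of summit and 26.4% of flank windows (exact McNemar test, adjusted p = 1.03e-29), and the sites GATA, GAGA, CA repeat, GC box and E-box were also more frequent at summits. The E-box lost its call with the 3772 strongest peaks and without replicate 1, and GAGA lost its call without replicate 1 and in distal peaks and turned with 50 bp on each side (2.53% against 2.54%). The Bicoid (4.31% against 7.09%) and Dorsal (1.07% against 1.66%) sites were less frequent at summits, with adjusted p of 8.42e-13 and 0.0046 in exact McNemar tests, while the Caudal site (4.61% against 4.76%) and the Twist E-box (7.04% against 6.52%) did not pass, with adjusted p of 0.793 and 0.298. Against weaker regions, however, both passed, the Caudal site as less frequent (4.61% against 5.76%) and the Twist E-box as more frequent (7.04% against 6.11%), with adjusted p of 0.00447 and 0.0493 in Fisher's exact tests. The Zelda site (4.27% against 5.09%, exact McNemar test, adjusted p = 0.0286) lost its call under each of the 8 alternatives run. The BEAF-32 pair and CRE lost theirs whichever replicate was left out. Against weaker regions with the same share of TSS summits, none of the 5 named motifs passed the threshold: DRE was in 2.33% of peaks and 2.07% of weaker regions, and Motif 1 in 1.46% and 1.28%. The Zeste site (35.2% against 33.5%, Fisher's exact test, adjusted p = 0.0567), GC box, CA repeat and E-box did not pass there either, while the single BEAF-32 site CGATA, Ohler motifs 6 and 7, GAGA and GATA did. In the 2656 distal peaks DRE and Motif 1 were not enriched, at 0.113% and 0.0753% of summits, whereas the Zeste site (35.1% against 24.5% of flanks) and the GC box (11.0% against 5.38%) were more frequent than in their flanks.

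**Figure D4:**
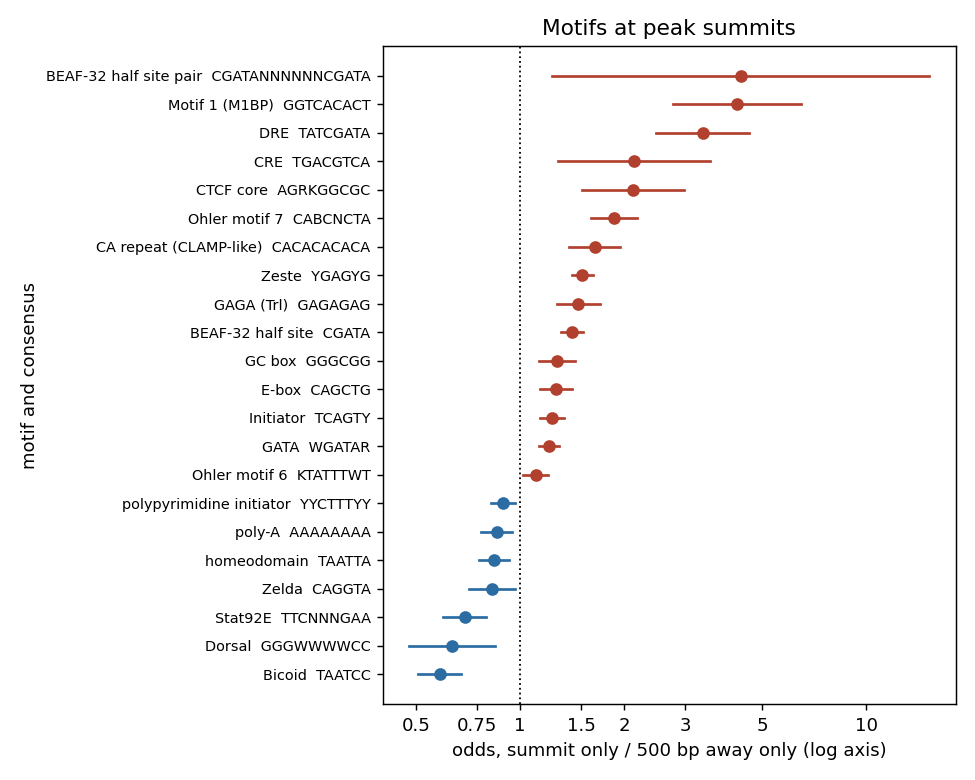
Odds of windows with the motif only at the summit against only 500 bp away (points, log axis) with 95% intervals (lines) for the 22 motifs past the threshold, with consensus sequences at the left. The 15 motifs above the dotted line at 1 are led by the BEAF-32 pair at 4.33 and Motif 1 at 4.23, and Bicoid is lowest at 0.586.

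Among the 2080 distinct 6-mers, 139 were more frequent at summits in both sets of arms and 186 were less frequent. The 5 with the largest odds were CCCCCC, CGATAG, GCCCCC, AGGGGG and CGAGCG, counted with their reverse complements. A run of 6 C or G was in 8.10% of summit windows and 3.42% of flank windows, odds of 2.54 (95% interval 2.18 to 2.96), with an adjusted p of 6.37e-25 in the finding arms and 2.24e-08 in the testing arms in exact McNemar tests. CGATAG, which overlaps DRE, was in 9.49% and 4.69% of windows, odds of 2.15 (95% interval 1.88 to 2.46). The lowest odds belonged to CCAGGA, in 1.95% of summit and 7.32% of flank windows, odds of 0.247 (95% interval 0.204 to 0.299). The count of more frequent 6-mers fell to 44 with the 3772 strongest peaks, to 71 without replicate 1 and to 89 without replicate 3.

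The replicates shared most of their strongest regions. Of the 7545 strongest regions, 64.2% were shared between replicates 1 and 2, 66.3% between 1 and 3 and 75.1% between 2 and 3, a mean of 68.5% ± 5.79 (SD over 3 pairs). Shifted regions shared 2.16% on average and 2.69% at most. Of the IDR peaks, 4214 (55.9%; 95% interval 54.7 to 57.0%) were recovered among the strongest regions of all 3 replicates, and 34 in none. Spearman's rho of signal across peaks, which are not independent replicates, was 0.448 for replicates 1 and 2, 0.452 for 1 and 3 and 0.704 for 2 and 3. All replicates were called against the same control alignment, so part of the overlap above the shifted value may come from the shared control. On dm3, the same replicates gave 6737 IDR peaks, and the dm6 count was 1.12 times as high. The ratio lay between 1.11 and 1.13 on 2L, 2R, 3L, 3R and X, and chromosome 4 had 20 peaks on dm6 and 13 on dm3.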

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

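Across the 15 main results, 81 of 114 alternative settings were counted as unchanged. That means the same direction, the same side of the threshold or, for values and counts, about the reported size. Counts were taken as kept up to a 1.5-fold change, such as 5 higher lists against 7, with 4 of the 7 among them. Values with an SD were taken as kept within it, such as a Spearman's rho of 0.448 against a mean of 0.535 ± 0.146 (SD). For overlap and rho, leaving out a replicate only returns the values of single pairs. The 81 therefore overstates how stable the results were. Every alternative run left TSS peaks above and intergenic peaks below the background, head-to-head genes above other genes, and TSS peaks above distal peaks in signal. The cause of the changes below was not tested, except that settings which drop peaks can keep or lower a share of bound genes but never raise it. Overlap of replicates was 59.4% with summits within 100 bp, 74.3% within 500 bp, and 64.2 to 75.1% with each replicate left out in turn. Recovery in all replicates was 87.1% for the 3772 strongest peaks, 46.2% within 100 bp, 63.0% within 500 bp, 62.2% for intervals that share 1 bp, and 62.9 to 71.0% in pairs of replicates. Spearman's rho was 0.448 to 0.704 with each replicate left out, highest without replicate 1. The share of bound protein-coding genes was 17.6% with the 3772 strongest peaks, 22.0% with a TSS distance of 200 bp, 31.7% with 1000 bp, and 18.2 to 22.5% with each replicate left out.

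The small difference between X-linked and autosomal genes (0.145 percentage points) turned to -2.25 with the 3772 strongest peaks, -1.16 with a TSS distance of 200 bp and -0.111 with 1000 bp. With each replicate left out it lay between -1.17 and 0.747, below 0 without replicate 1. Higher lists fell from 7 to 1 and lower lists from 6 to 2 against genes with a pooled region, where histone, testis and eggshell genes have no member and could not be tested. The higher count was 4 to 5 with each replicate left out. It was 4 with peaks recovered in all 3 replicates, an alternative chosen after seeing the data. More frequent motifs fell from 15 to 6 in distal peaks and to 7 against weaker regions, of which 5 were among the 15. More frequent 6-mers fell from 139 to 44 with the 3772 strongest peaks, 65 with 50 bp on each side, 76 in distal peaks and 71 to 124 with each replicate left out. The mean rank of the CG10543 promoter region became 10749 with 200 bp.

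Among single lists, motifs and named peaks, 599 of 706 settings kept their call. Among results that passed in the main analysis or in the alternative, directions turned for mitochondrial ribosomal protein genes with the nearest TSS only (19.2%, chosen after seeing the data). In distal peaks they turned for DRE (0.113% of summits), Motif 1 (0.0753%), Ohler motif 6 (19.3%), the Initiator (17.6%) and the TATA box (14.2%). Against weaker regions they turned for the BEAF-32 pair (0.172% of summits), the Initiator (20.2%) and the homeodomain site (11.2%), and with 50 bp on each side for GAGA (2.53%). The TATA box, not called in the main analysis, was more frequent at summits with the 3772 strongest peaks (17.7% against 14.8%), without replicate 1 (17.9% against 15.1%) and against weaker regions (13.1% of those). Translation factor genes lost their call whichever replicate was left out, and nuclear receptor and Polycomb and Trithorax group genes lost it with only the most 5' TSS of each gene, also chosen after seeing the data (adjusted exact p = 0.143 and 0.0673). No read counts were given, so the effect of depth could not be measured.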

Other observations

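The tests in this part were chosen after the results of the report had been seen, and the bounds for each explanation were set before its own test was run. The interval of the coding-sequence test was added after its value was seen.

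Peaks at TSSs and distal peaks held different motifs. DRE was in 4.09% of 4129 TSS summits and 0.113% of 2656 distal summits (Fisher's exact test, adjusted p = 2.92e-31), and Motif 1 in 2.59% and 0.0753% (Fisher's exact test, adjusted p = 6.4e-20). The BEAF-32 site CGATA was in 35.1% and 23.8% (Fisher's exact test, adjusted p = 4.3e-22), and Ohler motif 7 in 8.79% and 3.28% (Fisher's exact test, adjusted p = 1.41e-19). Distal summits more often held the GC box, 11.0% against 6.85% (Fisher's exact test, adjusted p = 1.76e-08), the GATA site, 40.2% against 33.98% (Fisher's exact test, adjusted p = 1.29e-06), and the Pho site, 21.3% against 17.2% (Fisher's exact test, adjusted p = 0.000127). The Pho site was not enriched at distal summits over their own flanks (22.1%, exact McNemar test, adjusted p = 0.717). Of the 34 motifs, 10 were more frequent at TSS summits and 6 at distal summits. The CTCF core did not differ past the threshold (1.36% and 1.47%, Fisher's exact test, adjusted p = 0.912). The same comparison was not made among weaker regions, so these differences cannot be told from those between TSS and distal sequence in general. Against weaker regions with the same share of TSS summits, DRE (2.33% against 2.07%) and Motif 1 (1.46% against 1.28%) did not pass.

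Noncoding RNA genes were bound at a share of 11.5% (376 of 3261), small nucleolar RNA genes at 8.55% (23 of 269) and pseudogenes at 4.85% (13 of 268), while 0 of 99 ribosomal RNA genes were bound, repeated copies in which reads are hard to place, so that this value is uncertain. On chromosome 4, 10 of 80 protein-coding genes were bound, 12.5%, against shares of 26.1 to 28.9% on the other arms. The chromosome 4 share was 16.25% ± 7.81 (SD, n = 3) in single replicates, and the difference was not tested. Peaks gathered in some places: 12 summits lay between 19012136 and 19022039 on 2L, beside CG15172 and over lncRNA:CR44184 and lncRNA:CR45292. There were 11 between 2748725 and 2757482 on 2L, over Pgk and Bacc, 11 between 12003285 and 12012318 on 2L around Rh5, 11 between 624563 and 633692 on 3L over lncRNA:CR43334, and 11 between 9428326 and 9438050 on 3R over ps. Replicate 2 listed 234 regions on chromosome 4 among its 30000, replicate 1 listed 71 and replicate 3 listed 46. Of those of replicate 2, 201 lay below its 7545 strongest regions.

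Gapdh2 and Eno, both genes of glycolysis, were among the 20 strongest peaks, which led to the hypothesis that genes of glycolytic enzymes may be bound more often than others. In a list of 13 such genes written before the test, 8 were bound. Without Gapdh2 and Eno, 6 of 11 were bound (Ald1, Hex-A, Ldh, Pglym78, Pgk and PyK), 54.5% against 27.9% of other protein-coding genes (two-sided Fisher's exact test, p = 0.0841). That misses the threshold and leaves the hypothesis open with so few genes.

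Runs of 6 C or G had the largest odds of all 6-mers more frequent at summits, and technical explanations were weighed. If every region the caller lists held such runs, weaker regions would hold them nearly as often. The runs were in 8.10% of peaks and 6.98% of 8835 weaker regions with the same share of TSS summits. The odds ratio of 1.17 (95% interval 1.04 to 1.32) was under the bound of 1.2 set for this explanation. Its interval, however, excluded 1 and reached past 1.2. The weaker regions came from the same precipitations and may hold weak binding. The test therefore cannot separate a property of the list from a preference of CG10543. High GC content of the summit windows, 42.8% against 41.5% in the flanks, stays open: in 1299 pairs whose GC differed by at most 3 percentage points the odds were 1.45 (95% interval 1.03 to 2.05), between the bounds of 1.2 and 1.5. A preference of CG10543 itself for such sequence was not tested, since samples without the tagged protein were not analysed here.

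The 186 6-mers less frequent at summits, such as CCAGGA, had median odds of 0.692, and coding sequence in the flanks was a candidate cause, since 23.9% of flank windows and 4.92% of summit windows held coding bases. In 5553 pairs with no coding base in either window the median odds were 0.774 (95% bootstrap interval 0.757 to 0.792), short of the value of 0.846 that would mark the midpoint to 1. Coding sequence could thus account for a part of the pattern. Whether it accounts for most cannot be told here. The 186 6-mers were chosen as less frequent in windows that include these pairs, which holds their odds down. CCAGGA was in 1.82% of summit and 4.0% of flank windows in the pairs with no coding base, against 1.95% and 7.32% in all pairs. No biological explanation was tested.

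Replicates 2 and 3 shared 9.85 percentage points more of their strongest regions with each other than with replicate 1 on average. Replicate 1 also had the lowest shares of head-to-head genes (33.4%) and of mitochondrial ribosomal protein genes (30.1%, against 49.3% and 54.8%). For other lists it had the highest share, such as heat shock genes (60%, against 35% and 40%) and transfer RNA genes (15.2%, against 9.66% and 8.62%). Regions on X and chromosome 4 do not account for the gap, which was 10.05 ± 0.688 percentage points (counting error) without them. Shifted summits do not account for most of it either, since it was 7.36 ± 0.593 points with summits up to 500 bp apart. A difference in depth or in the strength of the precipitation could lie behind it and stays open, because the files give no read counts, and no biological explanation was tested.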
